A study of Gallus gallus with 4 samples.

How the data were processed

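Messenger RNA was profiled by RNA sequencing in primary granulosa cells of the chicken, the somatic cells that surround the oocyte in the ovarian follicle. Per the labels' protocols, cells came from hens of 26 weeks, either from small yellow follicles before selection into the hierarchy (prehierarchical) or from the F2 to F4 follicles of the hierarchy (preovulatory). They were grown in M199 medium with 5% serum at 39°C, transfected after 18 h with a pcDNA3.1 plasmid that carries FOXL2 or with the empty plasmid, and collected 48 h later. FOXL2 is a forkhead transcription factor of granulosa cells and of ovarian development. The design has 4 groups with 1 library each, and whether a library holds 1 culture or a pool is not given in the sources used here.

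The authors deposited 1 table per library with an FPKM value (fragments scaled by transcript length and by the number of mapped fragments) for each Ensembl gene, per the file headers. Per the submitters' processing notes, Bowtie, RSEM and genome build galGal4 were used; versions and parameters are not given in the sources used here. The deposited tables list only genes with an FPKM of at least 0.01, so a gene missing from a table was taken as 0. No fragment counts were used, so absolute depth is unknown. RSEM shares fragments between similar transcripts, so genes with near-identical copies carry an uncertainty that the FPKM values do not show, and strand use is not stated.

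Low FPKM values nevertheless fall on steps, because each is a small number of fragments. Among single-transcript genes listed for 3 of the 4 libraries with values from 0.15 to 3 FPKM, 69.0%, 76.5% and 80.3% of the ratios of the other libraries to the preovulatory control lay within 0.06 log2 units of a fraction such as 1/2, 2/3 or 1, after the shift between libraries was removed. The same share was 22.3% to 23.4% for genes of 10 to 30 FPKM. The shift was the median of only those ratios already close to 1, so it could not show a large difference in depth. Within that limit, the preovulatory FOXL2, prehierarchical control and prehierarchical FOXL2 libraries had 1.00, 1.04 and 1.04 times the depth of the preovulatory control. The smallest step was read from 490 single-transcript genes of any level, missing from at least 1 table, whose lowest listed values were nearly equal. It had a median of 0.21 FPKM (quartiles 0.12 and 0.36), so that for them 1 FPKM stands for about 4.76 fragments and 5 FPKM for about 23.8.

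Before the data were examined, the filter was set at a mean of at least 1 FPKM over the 4 libraries, which kept 10639 of 13819 genes. Each pair of libraries was compared by the log2 ratio of (FPKM + 1), with no further scaling, and genes at least 2-fold apart on that scale were counted. With 1 library per group these counts are descriptions by size and carry no p-value. A ratio on this scale understates the change of low genes. The difference between the FOXL2 log2 ratios of the 2 phases was counted from 4-fold upwards. The test set before the data were examined was an additive model of phase and plasmid over the 4 libraries in limma 3.58.1 (R 4.3.3), with moderated variances that follow the mean and Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom per gene, so the gap between the plasmid ratios of the 2 phases serves as its error, and its p-values do not measure the spread between animals or cultures. On simulated data for the plasmid contrast, with 10639 genes and the observed spread of that gap by level, limma recovered 91% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and called 8 unchanged genes. The changed genes were drawn from those with higher expression. All simulated genes of a level shared 1 noise SD, whereas the observed spread also differs between genes of a level. The recovery is therefore no measure of power in these data, and 0 calls there would not exclude a shared difference. Other values were computed in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

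None of the 13819 gene identifiers or 14609 transcript identifiers matched the reference gene table used here, in which no gene carries an Ensembl identifier. Gene symbols were therefore not assigned, and no coordinates are printed. The 27 gene lists fixed before the data were examined (steroidogenesis, cholesterol synthesis, gonadotropin signalling, the transforming growth factor beta superfamily, cell cycle, extracellular matrix, interferon response, markers of theca, endothelial, immune, erythroid, epithelial and germ cells, and others) were not analysed here, nor were the levels of FOXL2, FSHR, STAR, CYP11A1 and CYP19A1. The rule fixed for named genes asked for symbols. In its place, chosen after the tables were seen, the 2 highest and 2 lowest ratios of each main comparison are printed by identifier, among genes with a mean of at least 5 FPKM that both tables list.

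The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, a median log2 ratio of 0, scaling by a trimmed mean of log ratios with equal weights (30% and 5% trimmed at each end), a 4-fold threshold, limma without the mean trend, and, added later, genes listed for all 4 libraries removal of a trend on expression level, and a limma contrast of the preovulatory control and prehierarchical FOXL2 libraries with the other 2, with phase in the model and the plasmid difference as error.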

Results

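The 4 libraries cover 2 phases of follicle growth, each with the FOXL2 plasmid and the empty control plasmid. The tables listed 12709 genes for the preovulatory control, 12600 for the preovulatory FOXL2 library, 12724 for the prehierarchical control and 12705 for the prehierarchical FOXL2 library. Between 10426 and 10549 genes reached 1 FPKM in a library, and between 837 and 869 reached 100 FPKM. The 100 most abundant genes of each library held 31.4% and 30.6% of all FPKM in the preovulatory control and FOXL2 libraries, and 32.2% and 34.3% in the prehierarchical ones. The median FPKM of listed genes was 13.3 and 13.7 in preovulatory cells against 11.6 and 10.8 in prehierarchical cells. Each group had 1 library, so no value below has a replicate error. FPKM steps in low genes put the depths of the 4 libraries within 1.04-fold of the preovulatory control. That estimate used only ratios already close to equal, so it could not show a large difference, and similar depth is not established. The level of the transfected gene itself is not analysed here, so the plasmid labels stand without a check from the transgene.

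The first question was how the FOXL2 library of prehierarchical granulosa cells differs from its control library. With the FOXL2 plasmid, 113 genes were at least 2-fold higher and 70 at least 2-fold lower than with the control plasmid, together 1.72% of 10639 genes. The more abundant genes among them lay on 1 side: of the genes with a mean of at least 30 FPKM, 23 were higher and 0 were lower. The genes that were higher held 0.53% of all FPKM with the control plasmid and 1.39% with FOXL2. ENSGALG00000011668 had the highest ratio, at 36.1 FPKM with FOXL2 against 1.24 with control, a log2 ratio of 4.05. ENSGALG00000023622 followed with 18.5 against 0.92 FPKM, a log2 ratio of 3.35. Among genes with a mean of at least 5 FPKM that both tables list, the lowest ratios belonged to ENSGALG00000028144, at 0.90 against 9.99 FPKM and a log2 ratio of -2.53, and to ENSGALG00000028667, at 1.14 against 10.2 FPKM and a log2 ratio of -2.38; over all genes the lowest log2 ratio was -3.28. The folds of these 4 genes moved by more than 1.5 times with the pseudocount: with 5 FPKM the log2 ratios were 2.72, 1.99, -1.35 and -1.30 in the order given. Of the genes counted, 49 of the higher and 52 of the lower had a mean under 5 FPKM, and 13 and 17 were missing from 1 of the 2 tables. With a pseudocount of 0.1, which gives low genes more weight, the counts were 196 higher and 194 lower.

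In preovulatory cells, 53 genes were at least 2-fold higher with FOXL2 and 101 were at least 2-fold lower, 1.45% of the same 10639 genes. At 4-fold the split turned to 8 higher and 4 lower. With a pseudocount of 0.1 the 2-fold counts were 163 higher and 216 lower, and with 5 they were 7 and 20. Among those with a mean of at least 30 FPKM, 2 were higher and 12 were lower. The genes that were lower held 0.73% of all FPKM with the control plasmid and 0.31% with FOXL2. Among genes with a mean of at least 5 FPKM that both tables list, ENSGALG00000013033 was lowest relative to control, at 12.6 against 56.5 FPKM and a log2 ratio of -2.08. ENSGALG00000007785 stood at 8.65 against 39.4 FPKM, a log2 ratio of -2.07. At the other end of such genes, ENSGALG00000026533 reached 20.5 FPKM with FOXL2 against 4.94 with control, a log2 ratio of 1.86, and ENSGALG00000027059 reached 5.26 against 0.89 FPKM, a log2 ratio of 1.73. Over all genes the log2 ratios ran from -3.32 to 4.89. The ratio of ENSGALG00000027059 dropped to 0.80 with a pseudocount of 5 FPKM. A mean under 5 FPKM was found for 37 of the higher and 56 of the lower genes, and 16 and 11 were missing from 1 of the 2 tables.

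**Figure D1:**
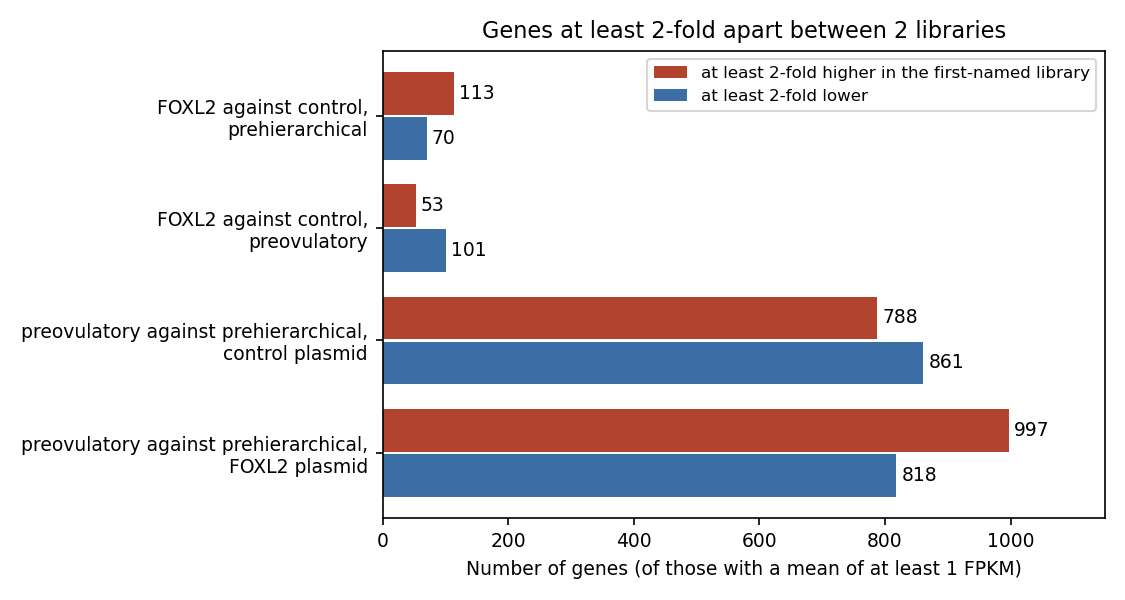
Number of genes (horizontal axis) at least 2-fold higher (red) or lower (blue) in the first-named library of each pair, among 10639 genes with a mean of at least 1 FPKM. Each bar compares 1 library with 1 other and has no error; the phase comparisons held 1649 and 1815 genes against 183 and 154 for the plasmid comparisons.

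The next question was whether the FOXL2 libraries differ from their controls alike in both phases. The FOXL2 log2 ratios of the 2 phases share no library, so the noise of a shared library does not make them correlate. Genes can vary together between cultures, however. With 1 library per group, the range of correlations without a FOXL2 effect is unknown. Across 10639 genes they were negatively correlated, with a Pearson r of -0.35 and a Spearman rho of -0.32; genes are not independent replicates and no p-value is given. Of the genes 2-fold apart in both phases, 39 went in opposite directions and 9 in the same direction. Independent lists would give 1.42 and 1.23, but that expectation ignores level and is too low, since both lists favour low genes. At 1 to 3 FPKM, 5.35% of genes were 2-fold apart in prehierarchical and 4.73% in preovulatory cells. At 30 to 100 FPKM these shares were 0.63% and 0.31%. The counts of 39 and 9 depend on the pseudocount: with 0.1 they were 99 and 22, and with 5 they were 9 and 1. Most of the 39 (32 genes) were higher with FOXL2 in prehierarchical cells and lower with it in preovulatory cells, and 7 had the reverse pattern. ENSGALG00000011668, the gene with the highest prehierarchical ratio, stood at 5.52 FPKM with FOXL2 against 15.5 with control in preovulatory cells, a log2 ratio of -1.34. ENSGALG00000023622 had 0.47 against 2.39 FPKM there, a log2 ratio of -1.21. Likewise, ENSGALG00000013033 and ENSGALG00000007785, named above for their preovulatory ratios, had prehierarchical log2 ratios of 1.80 and 1.54.

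The correlation was more negative in abundant genes, although the gap between the 2 ratios was narrower there. The SD over genes of that gap divided by 2 fell from 0.39 at 1 to 3 FPKM to 0.21 at 100 FPKM and over. The Pearson r of the 2 phases' ratios was -0.20 for 1289 genes of 1 to 3 FPKM, -0.33 for 2284 genes of 3 to 10 FPKM, -0.38 for 3661 genes of 10 to 30 FPKM, -0.56 for 2557 genes of 30 to 100 FPKM and -0.55 for 848 genes of at least 100 FPKM. The SD of the prehierarchical FOXL2 log2 ratios over genes fell with level, from 0.53 in the lowest of these classes to 0.23 in the highest, and that of the preovulatory ratios from 0.48 to 0.25. The FOXL2 ratio of 72 genes was at least 4-fold higher in prehierarchical than in preovulatory cells, and that of 27 genes at least 4-fold lower; with a pseudocount of 0.1 the split was nearly even, at 151 and 118. At a mean of at least 30 FPKM these numbers were 15 and 0. On each side, 14 genes were missing from at least 1 table. The difference between phases has 1 library per cell and was not tested against replicates.

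**Figure D2:**
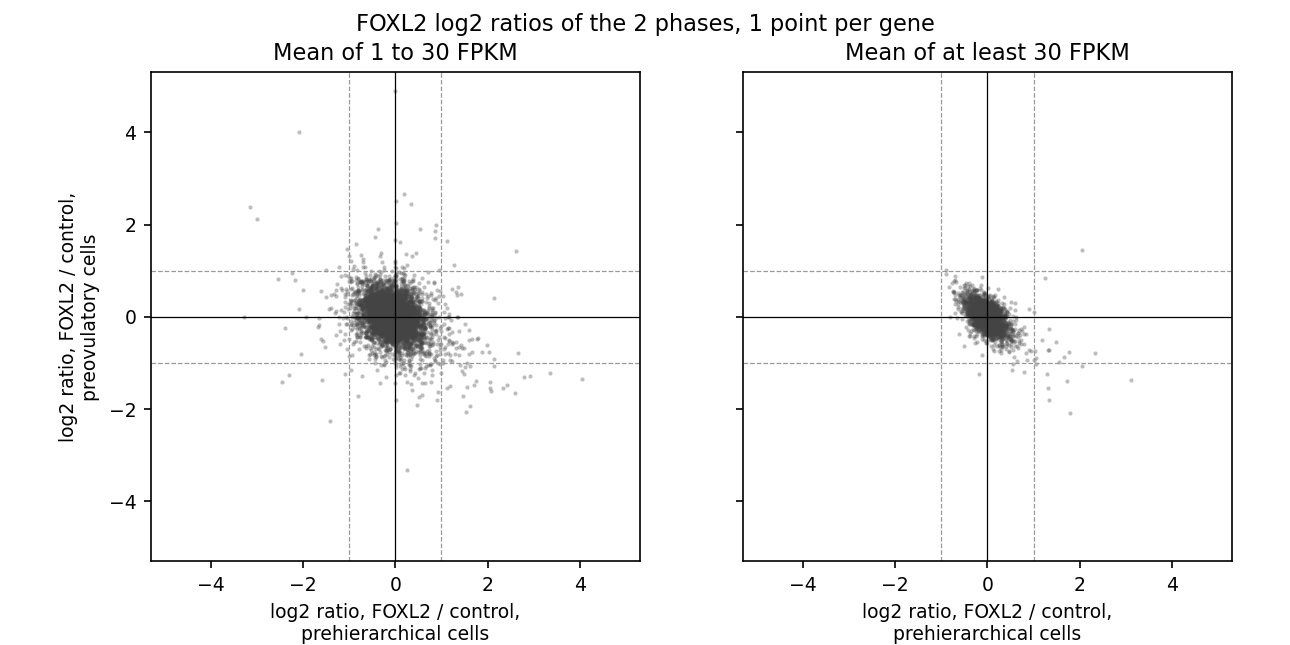
FOXL2 to control log2 ratio of (FPKM + 1) in prehierarchical cells (horizontal axis) against preovulatory cells (vertical axis), 1 point per gene, for genes with a mean of 1 to 30 FPKM (left) and at least 30 FPKM (right); dashed lines mark 2-fold. The points at 30 FPKM and above lie along a falling diagonal, with an r of -0.56 over 3405 genes.

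A plasmid difference alike in both phases was tested with the additive limma model. It called 0 genes at an adjusted p under 0.05 (smallest adjusted p = 1), and 112 of 10639 genes (1.05%) had an unadjusted p under 0.05, where chance gives 5%. The model takes the gap between phases as its error, and that gap was wider than the shared plasmid difference: the SD over genes of the gap divided by 2 was 0.28, against 0.20 for the mean of the 2 plasmid ratios. One abundant gene, ENSGALG00000021009, was the single gene with a mean of at least 30 FPKM that was 2-fold higher with FOXL2 in both phases, and it was singled out after its values were seen. It stood at 1747 against 418.2 FPKM in prehierarchical cells and at 1194 against 435.8 FPKM in preovulatory cells. Its limma estimate was a log2 difference of 1.76 (SE 0.19), with an unadjusted p of 1.35e-04 and an adjusted p of 1.

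Libraries of different phases differed far more than libraries of different plasmids, and phase cannot be told apart from a difference between cell preparations. With the control plasmid, 788 genes were at least 2-fold higher in preovulatory than in prehierarchical cells and 861 were at least 2-fold lower, together 15.5% of genes. With the FOXL2 plasmid the numbers were 997 and 818, or 17.1%. The genes higher in preovulatory cells held 10.1% of all FPKM there and 3.24% in prehierarchical cells with the control plasmid, and those higher in prehierarchical cells held 10.6% there and 3.41% in preovulatory cells. The widest gaps belonged to genes of prehierarchical cells: 13 genes were at least 16-fold lower in the preovulatory control, and 1 was at least 16-fold higher. ENSGALG00000022586 had 653.3 FPKM in prehierarchical and 3.36 in preovulatory control cells, a log2 ratio of -7.23, and its FOXL2 libraries had 814.9 and 4.36 FPKM. ENSGALG00000006992 had 335.6 against 2.48 FPKM, a log2 ratio of -6.60, with 347.2 and 2.99 FPKM in the FOXL2 libraries.

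The 2 genes with the highest preovulatory ratios in the control libraries, which were picked as extremes of that comparison, had lower ratios with FOXL2. ENSGALG00000006337 was at 185.6 FPKM in preovulatory and 4.08 in prehierarchical control cells, a log2 ratio of 5.20, but at 71.5 and 43.1 FPKM with FOXL2, a log2 ratio of 0.72. ENSGALG00000007785 was at 39.4 against 2.11 FPKM with the control plasmid, a log2 ratio of 3.70, and at 8.65 against 8.02 FPKM with FOXL2, a log2 ratio of 0.10. For most phase genes the 2 plasmids gave the same direction. The phase ratios of the control and the FOXL2 libraries, which share no library, had a Pearson r of 0.76 and a Spearman rho of 0.71 across genes. Both ratios were at least 2-fold higher in preovulatory cells for 406 genes and at least 2-fold lower for 569. Independent lists, without regard to level, would give 73.8 and 66.2. In opposite directions, 25 genes were 2-fold apart.

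**Figure D3:**
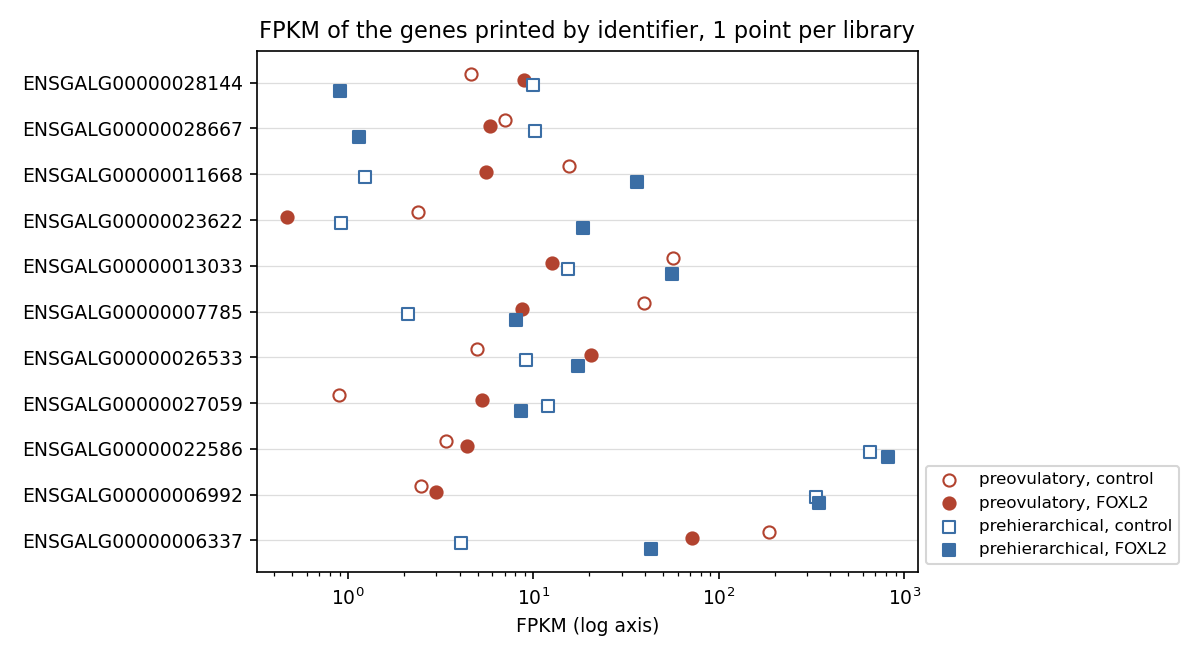
FPKM on a log axis of the 11 genes printed for the 3 main comparisons, with circles for preovulatory and squares for prehierarchical cells, open for the control and filled for the FOXL2 plasmid; each point is 1 library and has no error. ENSGALG00000022586 and ENSGALG00000006992 separate by phase with both plasmids, whereas ENSGALG00000011668, ENSGALG00000013033 and ENSGALG00000007785 differ between plasmids in opposite directions in the 2 phases.

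In the additive limma model, 2049 genes were higher and 1244 lower in preovulatory cells at an adjusted p under 0.05, 3293 of 10639 in all. Whether the libraries of a phase came from separate cell preparations is not given in the sources used here. A difference between preparations therefore cannot be told apart from phase, and the p-values of this model do not measure it. ENSGALG00000022586 had a log2 difference of -7.24 (SE 0.13, adjusted p = 6.7e-05) and ENSGALG00000006992 one of -6.52 (SE 0.14, adjusted p = 1.06e-04). ENSGALG00000006337 had a log2 difference of 2.96 (SE 0.96) and an adjusted p of 0.065, and ENSGALG00000007785 one of 1.90 (SE 0.78) and an adjusted p of 0.115; neither passed. The smallest p-values among genes higher in preovulatory cells belonged to ENSGALG00000008040, with a log2 difference of 3.29 (SE 0.12, adjusted p = 6.42e-04), and ENSGALG00000009095, with one of 3.50 (SE 0.18, adjusted p = 0.00127). The split between higher and lower genes depends on scaling, because the median log2 ratio between phases was 0.17 with the control and 0.23 with the FOXL2 plasmid. With those medians set to 0, 502 genes were 2-fold higher and 1098 lower in preovulatory control cells (31.4% higher, against 47.8% as deposited). With FOXL2 the counts were 561 and 1152 (32.7%, against 54.9%). The additive model, with the median log2 values of the libraries set equal, called 1060 higher and 1977 lower. Without the filter on low values it called 0 genes, with 4813 at an unadjusted p under 0.05.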

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

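The count of genes in opposite directions, the correlation and the limma test of the plasmid were set before the data were examined; the tests of a level trend, of exchanged labels and of the split of the marked libraries were chosen after the opposite directions had been seen. The number of genes 2-fold apart in opposite directions in the 2 phases, 39, was singled out because each phase's single library pair moved the other way; the difference between phases was not tested against replicates. For the same reason 4 of the genes printed for a FOXL2 comparison were singled out, by a rule that asked for at least 2-fold in both phases and opposite directions. Their prehierarchical minus preovulatory FOXL2 log2 ratio was 5.39 for ENSGALG00000011668, 4.55 for ENSGALG00000023622, 3.88 for ENSGALG00000013033 and 3.60 for ENSGALG00000007785. In these 4 the ratio was above 0 in prehierarchical and below 0 in preovulatory cells. ENSGALG00000006337, printed for the phase comparison and so outside that rule, went the same way with a difference of 4.48. ENSGALG00000028144 went the other way with one of -3.35, and was left out because its preovulatory log2 ratio of 0.82 is under 2-fold.

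The pattern is that the direction of variation that parts the preovulatory control and the prehierarchical FOXL2 library from the other 2 is wider than the direction that parts the plasmids, with an SD over genes of 0.28 against 0.20. With phase in the model, 1693 genes had an unadjusted limma p under 0.05 for this split against 112 for the plasmid, but each contrast serves as the error of the other, so these counts restate the negative correlation and decide nothing. A trend of the ratios on expression level is argued against as the whole cause, since the Pearson r was -0.344 after a running median on level was removed, against -0.346 before. A processing batch stays open: in the table headers the value columns of the same 2 libraries end in a number (1 for the preovulatory control, 2 for the prehierarchical FOXL2 library) and those of the other 2 do not. Whether these numbers mark a batch, a choice among replicates or neither is not given in the sources used here, and a batch along that split cannot be told apart from a phase-dependent response, because both are the same contrast of 4 libraries. An exchange of the plasmid labels in 1 phase, which would turn the correlation to 0.3465 by construction, and a response to FOXL2 that differs between phases, the biological explanation in the design, also stay open and untested, since the level of the transfected gene is not analysed here. Ordinary variation between single cultures, in genes that vary together, stays open as well, since each group has 1 library.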

How the results depend on the processing

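With 1 library per group no library could be left out with a test remaining. The additive limma fit holds phase as a term, so its plasmid contrast is already paired within phase, and no further pairing was possible with 1 library per group. The planned count-model and other-unit alternatives were not run, since no counts were used, and the gene list medians were not computed, since no symbols were assigned. Values near 1 FPKM rest on few fragments. The settings added later are the genes listed for all 4 libraries, the level trend and the split of the marked libraries. The negative correlation kept its sign and moved by less than 0.1 with both other pseudocounts, without the filter, with the filter at 5 FPKM, with genes listed for all 4 libraries and with the level trend removed, and the count of 0 genes for the plasmid stayed 0 in the 5 other limma fits chosen before the data were examined and with genes listed for all 4 libraries. The split that parts the preovulatory control and prehierarchical FOXL2 libraries from the others gave 92 and 56 in its place; it was chosen for its wider spread and takes the narrower plasmid difference as error, so calls are expected, and their total ran from 0 (no mean trend, or no filter) to 342 (filter at 5 FPKM). In all, 77 values kept within 1.5-fold of the reported count or within 0.1 of the reported correlation, and 45 moved further. Beside these, 3 limma counts were higher and 3 lower by more than 1.5-fold. The higher ones include both counts of that split, which is another contrast, so no plasmid count rose under another setting. The 77 include the plasmid limma counts that stayed 0. Of 48 ratios of single genes, 34 moved by less than 1.5-fold. Their signs could not reverse, since a pseudocount keeps the sign and the scaling shifts were smaller than these ratios.

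The values that moved follow, each with higher before lower; the cause was not tested beyond the construction of each setting (fewer or more low genes, a stricter threshold). With a pseudocount of 0.1, the FOXL2 counts were 196 and 194 in prehierarchical and 163 and 216 in preovulatory cells, the difference between phases gave 151 and 118, and 99 genes went in opposite and 22 in the same direction. With a pseudocount of 5, the FOXL2 counts were 38 and 6, and 7 and 20; the phase counts were 322 and 408 with control and 396 and 423 with FOXL2; the difference gave 22 and 3, and 9 genes went in opposite and 1 in the same direction. With the filter at 5 FPKM, the FOXL2 counts were 64 and 18, and 16 and 45; the lower phase counts were 540 and 533; the difference gave 43 and 9, and 24 genes went in opposite and 2 in the same direction. At 4-fold, the FOXL2 counts were 20 and 12, and 8 and 4, which turned the preovulatory split; the phase counts were 106 and 185, and 94 and 209; the difference at 8-fold gave 26 and 7. With the median ratio at 0, the higher phase counts were 502 and 561, and trimmed-mean scaling gave 593 higher with FOXL2. With genes listed for all 4 libraries, the difference gave 13 on the preovulatory side, and 2 genes went in the same direction. For phase, limma called 0 and 0 genes without the filter and 1060 and 1977 with equal medians.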

Other observations

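The tests on phase genes and FOXL2 ratios in this part were chosen after the ratios had been seen, and the test of abundant genes before its result was. Of 33 genes at least 4-fold higher in preovulatory cells with both plasmids, 0 were 2-fold apart between plasmids in prehierarchical cells and 2 were lower with FOXL2 in preovulatory cells. Of 115 genes at least 4-fold higher in prehierarchical cells with both plasmids, 1 was 2-fold higher with FOXL2 in prehierarchical cells and 2 were lower in preovulatory cells. Of all genes, 1.72% were 2-fold apart between plasmids in prehierarchical and 1.45% in preovulatory cells. The SD of the preovulatory FOXL2 log2 ratios was 0.42 and 0.41 in the 33 and 115 genes against 0.33 in all others, and that of the prehierarchical ratios 0.34 and 0.30 against 0.35. The selection asks for a large phase ratio with both plasmids, so it leaves out some genes with large plasmid ratios, and these counts are no property of phase genes. The 115 genes held 1.62% and 1.64% of all FPKM in the prehierarchical control and FOXL2 libraries and 0.15% in each preovulatory library.

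A hypothesis was that the FOXL2 plasmid moves cells of each phase towards the expression of the other, which could give opposite ratios. The phase difference averaged over both plasmids weighs each plasmid alike, so noise of equal size in the 2 libraries adds no correlation with the plasmid ratio. Across genes, the Pearson r with it was 0.0022 for the preovulatory FOXL2 ratio and -0.067 for the prehierarchical one (Spearman rho -0.0016 and -0.11). The hypothesis needs a clearly negative and a clearly positive value in turn, so these values argue against it.

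The median gene was higher in preovulatory than in prehierarchical cells, by 0.17 log2 units with the control and 0.23 with the FOXL2 plasmid, while the median of genes of at least 100 FPKM was lower, by -0.13 and -0.26. A few abundant genes taking more of the prehierarchical total could lower all other genes there. The 100 genes with the highest means held 31.8% of FPKM in the prehierarchical and 30.8% in the preovulatory control, and 33.9% and 29.9% in the FOXL2 libraries. With the totals of the remaining genes set equal, the control median was 0.141 and the FOXL2 median 0.22, so these 100 genes are not the whole cause. A shift spread over more genes, or a difference between the phases themselves, stays open and untested.

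Genes listed in 1 library and missing from the other library of the same phase mostly had low values. The step of 1 fragment was itself read from genes missing from a table, so nearness to it is no separate check. In prehierarchical cells 518 genes were listed with FOXL2 alone and 537 with control alone, with medians of 0.23 and 0.22 FPKM where listed. In preovulatory cells the numbers were 509 and 618, with medians of 0.22 and 0.24 FPKM. Some values were higher: in the same order, 32 and 40 prehierarchical and 33 and 39 preovulatory genes reached 1 FPKM. The highest were 6.57 and 8.71 FPKM in prehierarchical cells, and 28.7 and 9 FPKM in preovulatory cells.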
